A study of Homo sapiens with 24 samples.

How the data were processed

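The study measured polyadenylated RNA in 24 libraries from 6 liver cancer cell lines. Per the labels' protocols, RNA was extracted with Trizol, libraries were made with a VAHTS mRNA-seq kit and sequenced on an Illumina HiSeq X instrument. Per the submitters' processing notes, TopHat2 2.1.1 and Cufflinks 2.2.1 were used with the human build hg19. The annotation and the settings are not given in the sources used here. The deposited table is named as raw counts, but it holds FPKM: the values are not whole numbers, and in 293 genes with a single annotated transcript the value worth 1 read fell with transcript length with a log-log slope of -1.04. FPKM, as the authors deposited them, are fragments per kilobase of transcript, scaled to the mapped fragments of the library. Groups were taken from the sample titles, and the table's columns were matched to samples by name. The table also held 2 empty columns, which were not used.

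The analysis had been designed for a count test. Because FPKM are not counts, it was replaced by limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with the same samples and covariates. Estimates under 1e-06 were set to 0. Of 23284 rows, 1601 short RNA rows were left out, a choice made after the data were examined, since their FPKM is inflated by short length: MIR4461 alone took 33.6% to 51.6% of each library's sum. The other 21683 rows were kept. A gene was tested where at least 6 of the libraries compared had at least 1 FPKM. The fit had the cell line as a block, eBayes with a mean-variance trend and robust shrinkage, and Benjamini-Hochberg adjustment over all genes tested. Each comparison of 2 groups used their 12 libraries. The interaction used all 24 with line, line by siRNA and line by TGF-beta terms. Every fit had 5 residual degrees of freedom. A call is an adjusted p under 0.05.

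The lines pair the libraries, as the labels name the line of each. Deviations from the group means correlated between 0.873 and 0.977 for libraries of the same line. For the 180 pairs that differed in both line and group they correlated between -0.514 and 0.409. Of 24 libraries, 24 were nearest to a library of their own line. No 2 libraries held identical values. The labels name no batch and no separate cultures within a line.

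The depth behind FPKM was estimated from low genes, whose values are multiples of what 1 read is worth, with an assumed fragment length of 180 bases. It is approximate, was not used in the tests, and limits the precision of low genes most in the shallowest libraries. The median shift of a library against the mean of all libraries ranged from -0.13 to 0.12 on the log2 scale, and siSFPQ libraries lay lower: their knockdown comparisons had median changes of -0.07 and -0.09. Removing each library's GC trend moved these to 0.03 each.

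The 23 gene lists were fixed before the data were examined: TGF-beta targets, the TGF-beta cytostatic program, the TGF-beta apoptosis program, TGF-beta receptors and SMADs, BMP and ID targets, mesenchymal, epithelial, extracellular matrix, hepatocyte, oncofetal liver, G1/S and replication, G2/M, p53, homologous recombination, paraspeckle, integrated stress and unfolded protein, interferon, NF-kB, cholesterol synthesis, and glycolysis and hypoxia genes, and endothelial, stellate and fibroblast, and immune cell markers. SFPQ was in none. They were tested with camera (preset correlation 0.01), with estimated correlations and fry as alternatives, and adjusted over the lists of a comparison. Lists with fewer than 3 measured members were not tested. For 10 of them a score per line was computed, the mean log2 change over its genes, and tested with an exact two-sided sign-flip test over 64 flips. Relations over the 6 lines used exact tests over 720 pairings. Gene span, transcript length and GC content came from GENCODE annotation of another build, matched by symbol, and covered 96.3% of the genes tested in the knockdown comparisons. No coordinates from it were used.

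Named genes followed a rule written before the data were examined. It took SFPQ, and per comparison the 10 largest rises and 10 largest falls among called genes with a mean log2 level of at least 1 and the same sign in 6 of 6 lines. It also took the 2 to 4 members with the smallest p of each list described, and SMAD7, CDKN1A, CDKN2B and SMAD4 throughout. Some genes that the rule takes are not reported. Multicopy genes, Y-linked genes and XIST were passed over. BCYRN1 was counted as multicopy after its value was seen.

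The fit was tested on simulated data with the real line means and residual spread and with changes of known size added to some genes. In each comparison 67 genes were given a change of 0.5 on the log2 scale, and others a change of 1 or 2. Of the 67, it called 82.1% for TGF-beta in siCTL cells (12068 genes tested) and 71.6% in siSFPQ cells (11762 tested). It called 43.3% and 53.7% for knockdown without and with TGF-beta (11901 and 11921 tested) and 82.1% for the interaction (13440 tested). The changed genes were drawn at random from genes that were not low. These shares do not carry over to real responders: in siCTL cells 0 of 29 TGF-beta targets passed over all genes, at a median change of 0.49. Alternatives covered the pseudocount, the filter, the scaling, the shrinkage, short RNA rows, GC content, the block, an additive fit to all libraries, and leaving out lines.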

Results

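Gene expression was measured by RNA sequencing of polyadenylated RNA in 6 human liver cancer cell lines, Hep3b, Huh1, Huh7, HepG2, HLE and SK-HEP1. Each line was transfected with a control siRNA (siCTL) or with an siRNA against SFPQ (siSFPQ), a nuclear RNA-binding protein of paraspeckles, and was left untreated or given TGF-beta at 2 ng per ml for 24 hours. TGF-beta is a secreted growth factor that signals through SMAD proteins, among them SMAD4. The 4 groups held 6 libraries each, 1 per line, so the lines served as the replicates. The p-values of single genes and of the sign-flip tests measure the spread between lines. Those of camera set the changes of a list against those of the other genes. The table gives no counts. The depth of each library relative to the median library, estimated from the values of low genes, ranged from 0.352 to 1.73 times over the 24 libraries. It was lowest in Huh7 siSFPQ with TGF-beta (0.352) and HepG2 siSFPQ without it (0.395). Changes are given as log2 differences of FPKM + 1 with their standard error (SE), which understate the change of low genes.

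SFPQ was lower in the siSFPQ library than in the siCTL library of every line, with and without TGF-beta. Its level was 165 ± 59.5 FPKM (SD, n = 6) in siCTL cells and 37.2 ± 11.5 FPKM (SD, n = 6) in siSFPQ cells. With TGF-beta the levels were 158 ± 59.0 and 38.1 ± 10.4 FPKM (SD, n = 6 each). Without TGF-beta, HLE retained 9.49% of its SFPQ level and SK-HEP1 13.1%, while Huh1 and HepG2 retained 40.4% and 45.2%. The log2 change of SFPQ was -2.10 (SE 0.26, adjusted p = 0.00287) without TGF-beta and -1.97 (SE 0.25, adjusted p = 0.00241) with it, in 6 of 6 lines each. SFPQ did not pass the test for a TGF-beta response in siCTL cells (log2 change -0.07, adjusted p = 0.409) or in siSFPQ cells (0.05, adjusted p = 0.584).

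**Figure D1:**
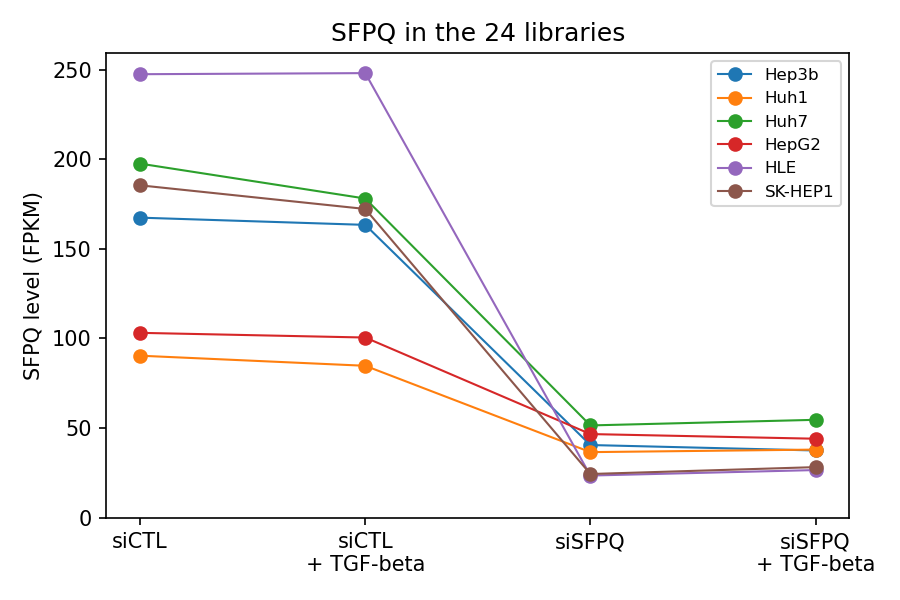
SFPQ level in FPKM (vertical axis) in the 24 libraries, by group (horizontal axis), with a point per library and a line joining the 4 libraries of each cell line. The siSFPQ libraries lie between 23.5 and 54.6 FPKM and the siCTL libraries between 84.7 and 248 FPKM.

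The first comparison asked which genes respond to TGF-beta in cells with normal SFPQ. TAGLN, an actin-binding protein, rose by 1.39 (SE 0.12, adjusted p = 0.0154), PDLIM7 by 0.85 (SE 0.10), the tropomyosins TPM1 by 0.80 (SE 0.09) and TPM4 by 0.46 (SE 0.06), and the integrin ITGA5 by 0.55 (SE 0.07). MEX3B (0.46), GABARAPL1 (0.36) and PDXK (0.33) rose as well. TMEM160 (-0.60), ENO1-AS1 (-0.59), UGCG (-0.37) and MCCC1 (-0.36) fell. These 12 genes, 8 higher and 4 lower, were the calls at adjusted p under 0.05 among 12164 tested. Each had the same sign in 6 of 6 lines. By limma 1909 genes had an unadjusted p under 0.05, where chance would give about 608. ENO1-AS1 overlaps ENO1, and the labels do not say whether the libraries keep strand.

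Of the 29 measured TGF-beta targets none passed the test over all genes, and 24 were higher with adjustment over the list alone. Among their smallest p-values were those of BHLHE40 (0.66), TGFBI (1.17) and PDGFB (1.15). The list stood above other genes with camera's preset correlation (adjusted p = 6.93e-21), and not with an estimated correlation (adjusted p = 0.0582). SMAD7, the inhibitory SMAD, had a change of 0.84 (SE 0.23, adjusted p = 0.149). In the cytostatic program, 0 of 15 genes passed over all genes and 2 adjusted over the list alone, GADD45B (0.97) and CDKN2B (0.73, SE 0.20), which encodes the CDK inhibitor p15. In HLE, CDKN2B was at 0.0357 FPKM or less in all 4 groups, so this line could hardly show a change of it in any comparison. CDKN1A, which encodes the CDK inhibitor p21, changed by 0.19 (SE 0.13, adjusted p = 0.481), and SMAD4 by 0.03 (adjusted p = 0.812).

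Of 19 measured mesenchymal genes 3 rose (TAGLN, TPM1 and ITGA5), and 11 were higher adjusted over the list alone. The list was called with the preset correlation (adjusted p = 1.54e-11) and missed the threshold with an estimated correlation (adjusted p = 0.0582). Extracellular matrix genes had 0 of 20 members past the test over all genes and 11 higher adjusted over the list alone, with COL1A1, the chain of type I collagen, at 2.05 and MATN3 at 0.55 (camera adjusted p = 1.27e-08, and adjusted p = 0.0582 with an estimated correlation). The 4 measured stellate and fibroblast markers, which share COL1A1 with that list, had 3 higher members adjusted over the list alone (camera adjusted p = 0.000301, and adjusted p = 0.307 with an estimated correlation). The G1/S and replication list was called lower (adjusted p = 0.000301, and adjusted p = 0.724 with an estimated correlation) with 0 of 30 members past the test over all genes. Adjusted over the list alone, 1 member was higher and 0 lower. Homologous recombination genes were called lower as well (adjusted p = 0.00172, and adjusted p = 0.620 with an estimated correlation), with 0 of 22 members past the test. By limma, leaving out Hep3b gave 16 calls, Huh7 or SK-HEP1 1 each, and Huh1, HepG2 or HLE 0 each, with 1382, 1332 and 1779 genes at an unadjusted p under 0.05.

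In siSFPQ cells the same treatment gave 613 calls among 11884 genes, 268 higher and 345 lower. Of these, 590 had the same sign in 6 of 6 lines. By limma 3353 genes had an unadjusted p under 0.05, where chance would give about 594. Among the largest rises were those of PMEPA1 (2.61, SE 0.50, adjusted p = 0.0339), COL1A1 (2.61, SE 0.46), the cytokine IL11 (2.26, SE 0.40), LMCD1, ANGPTL4 (2.14, SE 0.36), PDGFB (2.12), the metalloproteinase ADAM19 (1.80), GPR56 (1.75) and C1orf106 (1.67). The largest falls were of ABCC2 (-1.26, SE 0.18, adjusted p = 0.0263), ADORA2B (-1.03), RASL11A (-0.97), SH2D5 (-0.95), OSGIN1 (-0.93), CITED2 (-0.90), BIRC3 (-0.88), AVPI1 (-0.88), TXNRD1 (-0.87) and CYB5A (-0.80).

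Of 29 TGF-beta targets 16 rose and 0 fell, and 25 were higher adjusted over the list alone (camera adjusted p = 1.75e-22, and adjusted p = 0.0848 with an estimated correlation). Among the smallest p-values were those of RUNX1 (0.76), LTBP3 (0.76) and SKIL (1.65). SMAD7 missed the threshold (1.12, SE 0.27, adjusted p = 0.0541). In the cytostatic program GADD45B rose (1.21, SE 0.17, adjusted p = 0.0232). CDKN2B (0.78, adjusted p = 0.0576), GADD45A (-0.49), CDKN1B (-0.17), CDKN1A (0.07, adjusted p = 0.808) and SMAD4 (0.04, adjusted p = 0.728) did not pass. The cytostatic list was not called (camera adjusted p = 0.0551). In the apoptosis program, whose list was not called either (camera adjusted p = 0.398, with a mean change of 0.14 and a median of -0.06), 1 of 16 members passed over all genes, BMF, which rose. Of 18 receptors and SMADs 1 rose, ACVR1 (0.52), and 1 fell, TGFBR3 (-0.44), with 3 higher and 1 lower adjusted over the list alone, in a list that was not called (camera adjusted p = 0.381).

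Of 20 mesenchymal genes 9 rose, among them ITGA5 (1.09), ITGAV (1.23) and CALD1 (0.63), with 11 higher adjusted over the list alone (camera adjusted p = 1.82e-11, and adjusted p = 0.0859 with an estimated correlation). Of 19 matrix genes 3 rose, COL1A1, SPARC (0.74) and MATN3 (0.75), with 9 adjusted over the list alone. This list was called with the preset (adjusted p = 4.37e-08) and with the estimated correlation (adjusted p = 0.0308). The G1/S (MCM6 -0.31 and CDK4 -0.34 of 30 fell), G2/M (0 of 28) and homologous recombination lists (0 of 21) were called lower (camera adjusted p = 0.0122, 0.0332 and 0.0122), and none held with an estimated correlation (adjusted p = 0.723, 0.729 and 0.644). Adjusted over the list alone, these lists had 4, 0 and 5 lower members and 0 higher. Without Huh1 none of these 3 was called (camera adjusted p = 0.170, 0.570 and 0.0807), the mean G2/M change going from -0.15 to -0.05 and the mean G1/S change from -0.19 to -0.12, and without SK-HEP1 the G2/M list was not called either (0.0757). Stellate and fibroblast markers (2 of 3 rose, PDGFRB 1.25 and COL1A1) and glycolysis and hypoxia genes (2 of 27 rose, ANKRD37 0.61 and PFKFB3 0.65) were called higher (camera adjusted p = 0.00185 and 0.0311), and neither held with an estimated correlation (adjusted p = 0.0859 and 0.723). The glycolysis and hypoxia call was also lost without Hep3b, Huh7 or SK-HEP1 (camera adjusted p = 0.0643, 0.220 and 0.0646). Of 23 cholesterol synthesis genes 1 fell, with 6 lower adjusted over the list alone, and the list was called lower (adjusted p = 0.000487, and adjusted p = 0.644 with an estimated correlation). Of 19 NF-kB and inflammatory genes 3 fell and 0 rose, CXCL2 (-0.80), BIRC3 and SOD2 (-0.70), with 4 lower adjusted over the list alone, in a list that was not called (camera adjusted p = 0.381). In siCTL cells 0 of 18 passed over all genes, with 7 lower and 1 higher adjusted over the list alone, and the list was not called either (camera adjusted p = 0.0575). The count of calls was 24 without Huh1, 41 without HLE, 51 without HepG2, 68 without Huh7, 143 without SK-HEP1, 313 without Hep3b, and 39 without both Huh7 and HepG2. Scaling all libraries to a common median ratio turned the split of higher and lower calls from 268 and 345 to 303 and 109.

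The interaction asks whether the TGF-beta response differed between siSFPQ and siCTL cells, which is the question in the series title. It is signed: a larger response means a more positive change in siSFPQ cells, and a smaller one a more negative change. The TGF-beta targets responded more in siSFPQ cells: 17 of 29 members had a larger response adjusted over the list alone, 0 a smaller one, and 3 passed over all genes. These were ANGPTL4 (0.99, SE 0.13, adjusted p = 0.0197), RUNX1 (0.61, SE 0.09, adjusted p = 0.0333) and SKIL (0.60, SE 0.09, adjusted p = 0.0333), followed by PMEPA1 (0.87, adjusted p = 0.115). The list was called with the preset (adjusted p = 9.83e-23) and with the estimated correlation (adjusted p = 0.0413). The mean response of the list's genes was 0.64 in siCTL and 1.07 in siSFPQ cells, and the gain of 0.43 ± 0.18 (SD, n = 6) was positive in 6 of 6 lines. An exact two-sided sign-flip test over the lines gave p = 0.0312, the smallest it allows, and 0.156 after adjustment over 10 lists. Matrix genes, with 5 of 26 members larger adjusted over the list alone, were called with the preset (adjusted p = 1.44e-06) and the estimated correlation (adjusted p = 0.0413). Mesenchymal genes had 3 of 21 members larger adjusted over the list alone, ITGA5 (0.54), ITGAV (0.55) and MMP14 (0.26), and were called with the preset only (adjusted p = 1.29e-08, and adjusted p = 0.227 with an estimated correlation).

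**Figure D2:**
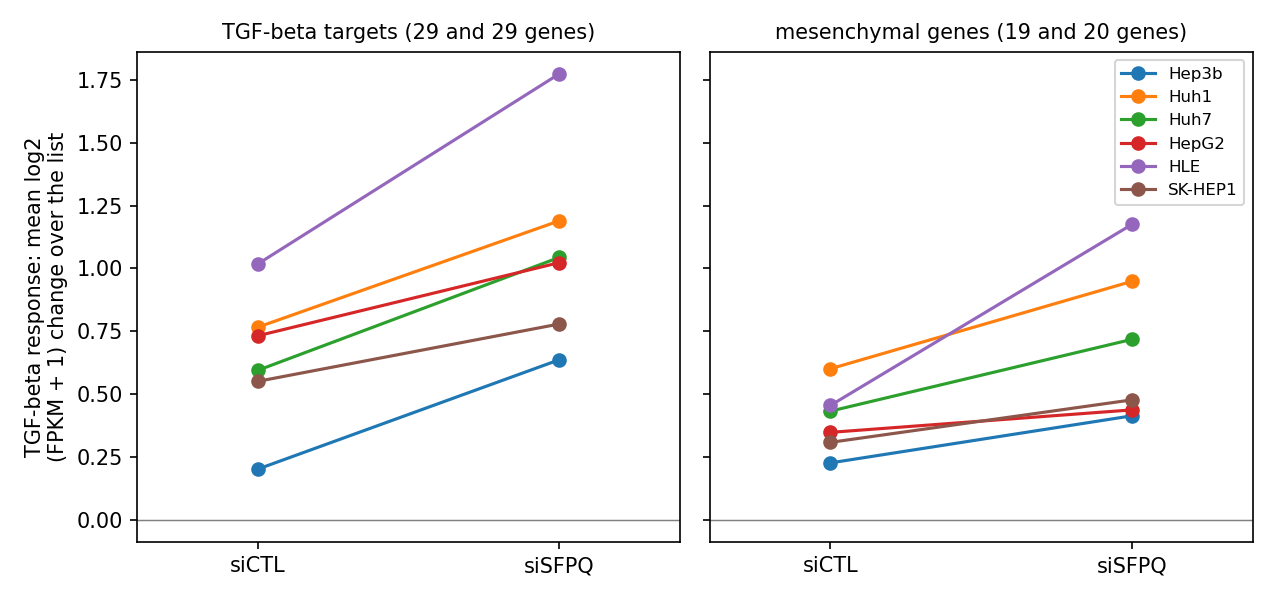
TGF-beta response of 2 gene lists (vertical axis, mean change in log2 of FPKM + 1 over the list's genes) in siCTL and siSFPQ cells (horizontal axis), with a point per cell line and state and a line joining both states of a cell line. For the TGF-beta targets the line of each of the 6 cell lines rises, by 0.23 in SK-HEP1 to 0.76 in HLE.

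The cytostatic program had no such gain. Its mean response was 0.15 in siCTL and 0.14 in siSFPQ cells, and 0.08 and 0.10 without Huh7, whose own values were 0.48 and 0.39. In the interaction 0 of 15 members passed by either adjustment, and the list was not called (camera adjusted p = 0.699, upward, with a median of 0.01 and a mean below 0). The interaction of CDKN1A was -0.12 (SE 0.07, adjusted p = 0.522), that of CDKN2B 0.05 (SE 0.09, adjusted p = 0.870), and that of GADD45B 0.24 (adjusted p = 0.267). SMAD7 (0.28, SE 0.08, adjusted p = 0.249) and SMAD4 (0.01, SE 0.08, adjusted p = 0.974) did not pass over all genes. Cholesterol synthesis genes had 12 of 23 members with a more negative TGF-beta change in siSFPQ cells adjusted over the list alone, among them DHCR7 (-0.26), EBP (-0.29) and MVD (-0.24) (camera adjusted p = 9.63e-09, and adjusted p = 0.235 with an estimated correlation). Interferon-stimulated genes had 3 of 24 such members, ISG15 (-0.40), OAS1 (-0.34) and OAS3 (-0.24) (camera adjusted p = 0.00266, and adjusted p = 0.235 with an estimated correlation). The mean TGF-beta change of the cholesterol list was -0.22 in siSFPQ and -0.03 in siCTL cells. That of the interferon list was -0.23 and -0.08. On average these were deeper falls and not weaker responses. Glycolysis and hypoxia genes, with ANKRD37 of 27 members past the test, and stellate and fibroblast markers, with 0 of 7, were called higher (camera adjusted p = 0.0109 and 0.0205), and neither held with an estimated correlation (adjusted p = 0.525 and 0.235). The former was lost without Hep3b (camera adjusted p = 0.318) and the latter without Huh7 (0.106).

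Across all 13496 genes tested, 34 had an interaction, 30 with a more positive and 4 with a more negative TGF-beta change in siSFPQ cells. The largest positive values were of NEDD8-MDP1 (1.79), LOC100652739 (1.34), TMEM160 (1.14, SE 0.10, adjusted p = 0.00199), ANGPTL4, PRR24 (0.95), PLSCR3 (0.88), the hypoxia-induced ANKRD37 (0.82), C4orf48 (0.79), GPR56 (0.76) and the transcription factor CEBPB (0.74). CYB5A (-0.54), MYL5 (-0.53) and APOBEC3C (-0.48) had more negative changes in siSFPQ cells, and so did BCYRN1 (-1.23). For CYB5A, which changed by -0.80 in siSFPQ cells, this was a deeper fall and not a weaker response. BCYRN1 has many near-identical copies, falls outside the rule for named genes and is named here after its value was seen. NEDD8-MDP1 is a read-through of 2 neighbouring genes and shares their sequence, so its value is uncertain, as is that of the uncharacterised LOC100652739. The count was 8 without Huh1, 10 without SK-HEP1, 11 without HLE, 13 without Hep3b and 22 without HepG2. An additive fit without line-specific effects called 0 genes, with 206 at an unadjusted p under 0.05.

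The TGF-beta responses of siCTL and siSFPQ cells came from separate libraries. All 8 genes called higher in siCTL cells were also called higher in siSFPQ cells, where 0.179 would be shared by independent lists, and 2 of the 4 lower genes were shared against 0.118. TMEM160, lower in siCTL cells, was called higher in siSFPQ cells (0.54, adjusted p = 0.0411). Of the 263 genes called higher in siSFPQ cells among the 11728 tested in both, 251 also had a positive change in siCTL cells.

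Knockdown of SFPQ without TGF-beta gave 2608 calls among 12011 genes, 804 higher and 1804 lower, 214 of them by at least 2-fold. The labels name no other siRNA against SFPQ and no rescue. Here, with TGF-beta and in the interaction, effects of the siRNA on other targets cannot be told apart from loss of SFPQ. The kinase MKNK2 (1.75, SE 0.24, adjusted p = 0.00376), HABP4 (1.68, SE 0.11, adjusted p = 0.000464), OGFR (1.49), the growth factor CSF1 (1.39), BICD2 (1.38), the phosphatases DUSP5 (1.32) and DUSP1 (1.20), FOXP4 (1.29), TBKBP1 (1.26) and the actin-binding DBN1 (1.20) rose most. Besides SFPQ, the co-chaperone PTGES3 (-2.21, SE 0.30, adjusted p = 0.00376), the microtubule regulator STMN1 (-2.11, SE 0.35), RTN3 (-1.98), C4orf34 (-1.84), TBC1D5 (-1.73), FAF1 (-1.69), DAP (-1.68), CFDP1 (-1.67) and TNPO3 (-1.65) fell most.

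Many cell cycle genes fell. Of 28 G2/M genes 24 fell and 0 rose, among them TOP2A (-1.46, SE 0.24, adjusted p = 0.00590), TPX2 (-1.39) and HMMR (-1.39), and all 28 were lower adjusted over the list alone. Of 30 G1/S and replication genes 18 fell and 1 rose, and 25 were lower adjusted over the list alone, with the cyclin CCND1 (-1.22), PCNA (-0.66), POLA1 (-1.08) and TK1 (-0.99) first. Of 22 homologous recombination genes 11 fell, among them FANCD2 (-1.24), RAD51B (-0.86), MRE11A (-0.59) and BRCA1 (-0.83), with 12 adjusted over the list alone. The camera adjusted p-values of these lists were 8.78e-09, 5.15e-06 and 9.49e-05. With estimated correlations, all were lost (adjusted p = 0.469 each). The size differed between lines: the mean G2/M change was -1.76 in HLE, -1.12 in SK-HEP1 and 0.07 in Hep3b. An exact sign-flip test gave p = 0.0625 for G2/M genes and 0.0312 for G1/S genes, each 0.156 after adjustment.

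**Figure D3:**
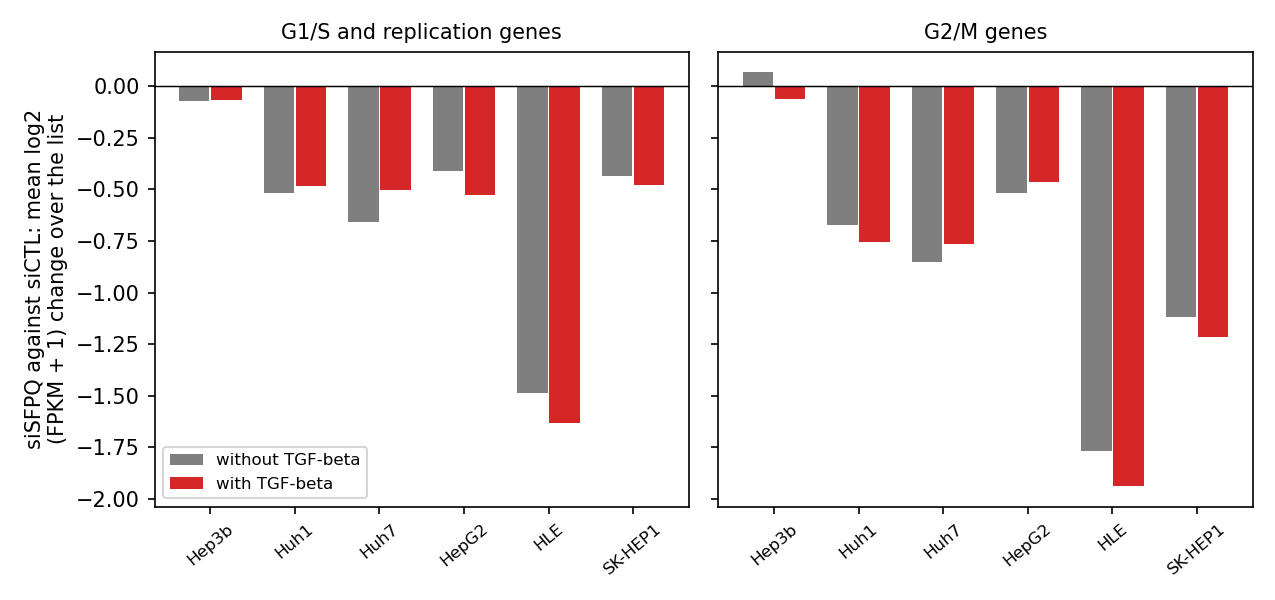
Change of 2 cell cycle gene lists on SFPQ knockdown (vertical axis, mean change in log2 of FPKM + 1 over the list's genes) in each cell line (horizontal axis), without and with TGF-beta (bar colours), with 1 pair of libraries behind each bar. HLE has the largest fall in both lists, -1.76 for G2/M genes without TGF-beta, and Hep3b lies near 0.

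NF-kB and inflammatory genes rose, 7 of 18 over all genes with 0 falls, and 7 higher and 1 lower adjusted over the list alone, with CSF1, RELB (0.58), NFKB1 (0.42) and NFKB2 (0.41) first (camera adjusted p = 1.58e-05, and adjusted p = 0.469 with an estimated correlation). Of 22 paraspeckle components 4 rose and 3 fell, the same by either adjustment and with a median of -0.10 in a list that was not called (camera adjusted p = 0.609, upward), with the scaffold RNA NEAT1 (0.82, SE 0.09, adjusted p = 0.00233), HNRNPH3 (0.65) and RBM7 (0.59) higher and TAF15 (-0.80) lower. Of 18 receptors and SMADs 2 rose, TGFBR2 (0.56) and TGFBR1 (0.40), and 1 fell, the BMP receptor BMPR2 (-1.44, SE 0.18, adjusted p = 0.00294), with 1 higher and 1 lower adjusted over the list alone, in a list that was not called (camera adjusted p = 0.200). Of 24 integrated stress and unfolded protein genes 3 fell, XBP1 (-1.50), DNAJB9 (-0.98) and PHGDH (-1.02), and 2 rose, among them DDIT4 (0.94), the same by either adjustment, in a list that was not called (camera adjusted p = 0.988). The cytostatic list (camera adjusted p = 0.0182), the epithelial list (0.0137) and the p53 targets (0.0319) were called higher, each with adjusted p = 0.469 with an estimated correlation. Without Huh7 the cytostatic list (camera adjusted p = 0.0710) and the p53 targets (0.0895) were not called, and without HLE neither were the epithelial list (0.0511) and the p53 targets (0.0834). None of the 15 cytostatic genes passed by either adjustment. Of 15 epithelial genes 3 rose and 0 fell, CLDN1 (0.46), OCLN (0.46) and TJP1 (0.27), which encode tight junction proteins, with 4 higher adjusted over the list alone. Of 22 p53 targets 5 rose, among them GDF15 (0.90) and TNFRSF10B (0.64), and 2 fell, among them RRM2B (-1.11), with 5 higher and 3 lower adjusted over the list alone. SMAD7 (-0.29, adjusted p = 0.148), CDKN1A (0.24, adjusted p = 0.240), CDKN2B (0.25, adjusted p = 0.247) and SMAD4 (0.06, adjusted p = 0.670) did not pass. The excess of falls depends on the scaling: with libraries set to a common median ratio, 1171 genes were higher and 1370 lower, and with each library's GC trend removed 1387 were higher and 1258 lower. The count was 1341 without HLE, 1369 without SK-HEP1 and 1661 without Huh7.

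With TGF-beta present, knockdown gave 3639 calls among 12021 genes, 1018 higher and 2621 lower. MKNK2 (1.69), ADAM19 (1.68), NBL1 (1.65), FOXP4 (1.57), the small GTPase RHOB (1.55), HABP4 (1.52), OGFR (1.51), B4GALT1, ANGPTL4 (1.48) and BICD2 (1.42) rose most. PTGES3 (-2.29), STMN1 (-2.10), RTN3 (-2.01), CFDP1 (-1.87), FAF1 (-1.82), TBC1D5 (-1.77), AKAP2 (-1.74), the methyltransferase SMYD3 (-1.71) and CMC1 (-1.66) fell most, besides SFPQ. Calls shared with the knockdown without TGF-beta numbered 594 higher and 1560 lower, where independent lists would share 67.8 and 396, with 11831 genes tested in both.

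Of 29 TGF-beta targets 15 rose and 1 fell, by either adjustment, with CTGF (1.07), ANGPTL4, TGFB1 (0.87) and CYR61 (1.36) first (camera adjusted p = 1.16e-08, and adjusted p = 0.185 with an estimated correlation). On knockdown without TGF-beta, 5 of 28 targets rose and 1 fell, by either adjustment, and the list was not called (camera adjusted p = 0.0711). Mesenchymal genes (6 of 20 higher and 2 lower, with 8 and 2 adjusted over the list alone; ITGAV 0.96, ITGA5 0.88) and matrix genes (4 of 22 higher and 1 lower, the same adjusted over the list alone; COL1A1 0.98, MATN3 0.54) had camera adjusted p = 0.000158 and 0.000128, and adjusted p = 0.303 and 0.185 with an estimated correlation. Of 28 G2/M genes 27 fell, TOP2A (-1.52) and TPX2 (-1.45) first, and of 30 G1/S genes 16 fell and 1 rose (CCND1 -1.37), with 28 and 21 lower adjusted over the list alone. Their camera adjusted p-values were 3.86e-07 and 0.000128, and adjusted p = 0.458 each with an estimated correlation. Of 23 cholesterol synthesis genes 13 fell and 1 rose, with 14 lower adjusted over the list alone, PMVK (-0.88), TMEM97 and MVK (-0.51) first (camera adjusted p = 0.00762, and adjusted p = 0.391 with an estimated correlation). Of 22 homologous recombination genes 13 fell (RAD51B -0.85, RAD51C -0.49), with 18 lower adjusted over the list alone, and of 18 NF-kB genes 5 rose (NFKB1 0.56, CSF1 1.20), the same adjusted over the list alone. Epithelial genes (2 of 15 rose, KRT8 0.57 and TJP1 0.45) and cytostatic genes (0 of 15) were called higher. The camera adjusted p-values of these 4 lists were 0.000128, 0.000392, 0.00456 and 0.00762, and with an estimated correlation adjusted p = 0.458, 0.303, 0.185 and 0.303. SMAD7 (-0.02, adjusted p = 0.934), CDKN1A (0.12, adjusted p = 0.570), CDKN2B (0.30, adjusted p = 0.0876) and SMAD4 (0.07, adjusted p = 0.515) did not pass. Median-ratio scaling gave 1581 higher and 1715 lower calls, and removing each library's GC trend gave 1836 higher and 1513 lower. The count of calls was 2315 without SK-HEP1.

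Within single lines, with no replicate, the number of genes with a mean of at least 10 FPKM and a change of at least 2-fold on TGF-beta ranged from 7 in Hep3b to 137 in Huh7 in siCTL cells, and from 35 in Hep3b to 311 in Huh7 in siSFPQ cells. On knockdown without TGF-beta it ranged from 49 in Huh1 to 688 in SK-HEP1. Over the 6 lines, the SFPQ level in siCTL cells did not relate to the response of the TGF-beta targets (Pearson r = 0.0201, exact permutation p = 0.976; Spearman rho = 0.0857, p = 0.919). The log2 change of SFPQ on knockdown, which is negative in every line, and the gain in response had r = -0.504 (exact permutation p = 0.326) and rho = -0.371 (p = 0.497). For the cytostatic program the same 2 relations had r = -0.135 and -0.133 (exact permutation p = 0.821 and 0.787) and rho = -0.429 and -0.257 (p = 0.419 and 0.658). After adjustment over the 4 relations every Pearson p was 0.976, and the Spearman p-values were 0.878 or more. Without the 2 lines farthest from the median of x, the 4 values of r were 0.983, -0.674, -0.0679 and 0.295, over 4 lines each, so the first rests on which lines are kept.

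SFPQ has been linked to transcription of long genes, and the knockdown change was therefore set against gene span. Across 11570 genes, which are not independent replicates, rho was -0.132 without TGF-beta. Per line it ranged from -0.271 in HLE to 0.0344 in HepG2 and was negative in 4 of 6 lines (mean -0.0824, exact sign-flip p = 0.156). With TGF-beta the mean was -0.0328, negative in 3 of 6 lines (exact sign-flip p = 0.469). Of the 2893 genes with the longest span 581 were called lower without TGF-beta, against 348 of the 2893 with the shortest. With TGF-beta the counts were 693 and 603. Given transcript length, the partial rho with span was negative in 6 of 6 lines in both states, with means of -0.114 and -0.0915 (exact sign-flip p = 0.0312 each, the smallest possible, and 0.219 after adjustment over the 14 tests of this kind).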

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

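The tests of other labellings, of GC content in the interaction and of shallow libraries were chosen only after the result was seen. Those of spread, the list's gain and gene span were set before their own values were seen, though responses of single genes, and long genes among the falls, had been seen by then.

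The TGF-beta response differed between siSFPQ and siCTL cells by the interaction test for 34 genes. Those named were NEDD8-MDP1 (1.79), LOC100652739 (1.34), TMEM160 (1.14), ANGPTL4 (0.99), PRR24 (0.95), PLSCR3 (0.88), ANKRD37 (0.82), C4orf48 (0.79), GPR56 (0.76), CEBPB (0.74), CYB5A (-0.54), MYL5 (-0.53) and APOBEC3C (-0.48). The genes with a positive interaction are GC-rich, with a median transcript GC content of 61.1% against 48.7% of all genes tested. Removing each library's trend on GC content left the median interaction of the 29 higher calls with a GC value at 0.64 (SD 0.29), against 0.60 (SD 0.30) before, which is 107% of it, with 20 of the 29 still called and 22 calls in all. This argues against a GC trend as the whole cause. The fit to the 4 lines other than Huh7 and HepG2, which hold the 2 shallowest libraries, called 14 genes, 10 of them among the 34, which argues against those libraries as the whole cause. A biological difference by SFPQ remains a hypothesis, since the calls were found and tested on the same libraries and their number depends on the fit. Only the real labelling, 1 of the 32 swaps of siRNA labels within lines, gave 34 calls, and the highest other gave 2. A share of 1 in 32 is the smallest these swaps can give. As the test was chosen after the count was seen, it argues against chance without excluding it.

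TGF-beta gave 613 calls in siSFPQ and 12 in siCTL cells. At an unadjusted p under 0.05 by limma the counts were 3353 and 1909, where chance would give about 594 and 608. The median absolute log2 change over 11728 genes was 0.122 in siSFPQ and 0.0734 in siCTL cells. The contrast of calls past the adjusted threshold therefore overstates the difference in response, and siCTL cells responded as well. The tables argue against a smaller spread between lines in siSFPQ cells: the median residual SD over 11728 genes was 0.141 there against 0.115, a ratio of 1.22. A larger response is a candidate explanation, and the TGF-beta targets, a list fixed beforehand, gained in 6 of 6 lines. Median-ratio scaling left 412 and 14 calls. Label swaps within lines were also made for the TGF-beta response in siCTL and siSFPQ cells and for knockdown without and with TGF-beta. Only the real labelling, 1 of 32, gave as many calls (12, 613, 2608 and 3639), and the highest other swap gave 0 in each. This is again the smallest share possible, from a test chosen after the counts were seen, so it argues against chance without excluding it. The 12 calls also went to 0 or 1 when any line but Hep3b was left out.

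The mean rho per line of the knockdown change with gene span was -0.0824 without TGF-beta and -0.0282 in genes with a mean of at least 10 FPKM, neither past its test. GC content may account for part or all of this: with the GC trend removed, the mean rho was -0.0397 in that state and 0.0194 with TGF-beta, -0.0101 over both. This met the bound set beforehand for GC content as the cause. With TGF-beta, however, the mean rho of -0.0328 met that bound with the GC trend left in. Meeting it therefore does not decide whether GC content is the cause. The tables argue against transcript length as the whole cause: the partial rho given it was -0.103 on average and negative in 6 of 6 lines in both states. This partial rho was taken with the GC trend left in, so it does not separate gene span from GC content. It was below -0.1 in 4 and 3 lines, short of the bound set beforehand, so this reading was chosen after the values were seen.

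In 11 of 164 sets of 6 lines examined, 1 line stood apart from the others by a gap beyond Dixon's critical share of the range, where chance gives about 8.2. HLE had the highest SMAD7 response to TGF-beta in siCTL cells (2.25, the others 0.19 to 0.86) and in siSFPQ cells (2.78, the others 0.41 to 1.03). HLE also had the lowest CITED2 response in siSFPQ cells (-2.13). On knockdown with TGF-beta HLE had the highest hepatocyte score (0.46) and the lowest G1/S score (-1.63). On knockdown without TGF-beta Huh7 had the highest change of SMAD7 (0.46) and of SMAD4 (0.39), and it had the lowest SMAD4 interaction (-0.29). Hep3b had the lowest CDKN1A change on knockdown with TGF-beta (-0.77). Huh1 had the lowest G2/M score in the TGF-beta response of siSFPQ cells (-0.64), and SK-HEP1 the lowest interaction of the apoptosis score (-0.0442).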

How the results depend on the processing

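DESeq2, limma-voom and the other normalizations of counts were not run, because they need counts, and the filter of 1 CPM in 6 libraries has its counterpart in the filter used. The pseudocount, the filter at a mean of 5 FPKM, both scalings, the shrinkage, the short RNA rows, the GC trend and the fit without Huh7 and HepG2 were chosen after seeing the data. In the order TGF-beta in siCTL cells, TGF-beta in siSFPQ cells, knockdown without and with TGF-beta, and interaction, the counts of calls were 12, 613, 2608, 3639 and 34. Without the low-value filter they were 0, 15, 1152, 2410 and 4, with 2199 genes at an unadjusted p under 0.05 in the first. Without the line as a block no gene was called in any of the 5 by limma (0 each, with 11, 47, 633, 734 and 6 at an unadjusted p under 0.05), and the SFPQ changes of -2.10 and -1.97 missed the threshold there and passed it under every other alternative. Without Huh7 and HepG2 they were 3, 39, 804, 1497 and 14, with fewer samples. An additive fit to all libraries gave 4 for the first and 0 for the interaction, with 206 at an unadjusted p under 0.05. Short RNA rows kept gave 1, 341 and 18 for the first, second and interaction; a GC trend removed gave 5 and 22, and no trend or robust shrinkage 1 and 15, for the first and the interaction; a pseudocount of 0.1 gave 13 for the interaction. Leaving out lines has fewer samples, and a fit without the block leaves the differences between lines in the residual. Without the low-value filter 19947 genes entered the adjustment in the first comparison, against 12164. The 12 and 613 calls of the first and second comparisons all kept their sign there. Causes of the other shifts were not tested. Leaving out each line gave 0 to 16, 24 to 313, 1341 to 2221, 2315 to 2952 and 8 to 28 calls. The share of lower calls was 56.3%, 69.2% and 72.0% for TGF-beta in siSFPQ cells and knockdown without and with TGF-beta, and 26.5%, 53.9% and 52.0% with median-ratio scaling, 29.8%, 63.4% and 64.8% with upper-quartile scaling. With the GC trend removed it was 35.2%, 47.6% and 45.2%. In siCTL cells it was 33.3%, and 21.4% and 11.1% with these scalings.

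Camera called 6, 9, 7, 10 and 7 lists, 0, 1, 0, 0 and 2 with an estimated correlation, and fry 3, 5, 0, 7 and 2. Leaving out each line gave 6 to 9, 6 to 11, 5 to 11, 10 to 12 and 7 to 8 lists. The mean scores of the TGF-beta targets kept their sign under every alternative run on them. With 5 lines the exact test cannot pass the threshold. The overlap at adjusted p under 0.1 was 73 higher and 25 lower genes for TGF-beta, against 8 and 2, and 945 higher for knockdown, against 594. The median number of genes changed at least 2-fold per line was 44.5, 165, 258.5 and 215.5, and 117.5, 342, 491.5 and 485.5 at a mean of at least 1 FPKM. The relation of the SFPQ change and the cytostatic gain turned from r = -0.133 to 0.296 with a pseudocount of 0.1 and to 0.295 without the 2 farthest lines. The mean rho with gene span in knockdown with TGF-beta turned from -0.0328 to 0.0308 in genes with a mean of at least 10 FPKM and to 0.0194 with the GC trend removed, none past its test. Of 112 values of named genes, 85 were called, and none changed sign in a call under any alternative. Genes taken for the same sign in 6 of 6 lines could not change it when lines were left out. Of the 85 calls, 5 were lost with median-ratio scaling, 36 without Huh1 and 36 without Huh7 and HepG2. Without the low-value filter 40 were lost, and without the block all 85. Depth limits low genes most in Huh7 siSFPQ with TGF-beta and HepG2 siSFPQ without it.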

Other observations

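Hepatocyte genes had 0 of 26 members called in the TGF-beta response of siCTL and of siSFPQ cells and on knockdown without TGF-beta, and 1 of 25, FOXA1 (-0.36), lower on knockdown with TGF-beta. Only 4 hepatocyte genes had at least 1 FPKM in all 24 libraries, so the lack of calls does not show that the others were unchanged. Oncofetal liver genes had H19 (0.54) higher and PEG10 (-0.51) lower on knockdown with TGF-beta, of 9 measured. Of 6 BMP and ID targets measured in the TGF-beta response of siCTL cells 4 were lower adjusted over the list alone, ID2 (-0.29), ATOH8 (-0.43), ID1 (-0.41) and ID3 (-0.43), and 0 over all genes by limma. These targets had ID1 (0.36) and ID3 (0.80) higher on knockdown without TGF-beta, of 7 measured. Glycolysis and hypoxia genes had VEGFA (-0.63), ALDOC (-0.32) and BNIP3 (-0.37) lower on knockdown without TGF-beta, of 27 measured. Endothelial markers had 2 or 3 of 14 members measured, ESAM (0.72) being higher on knockdown with TGF-beta. Immune cell markers had 2 or 3 of 14 measured, CD68 (0.36) being higher on knockdown without TGF-beta.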
